A study of Mus musculus with 30 samples.

How the data were processed

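RNA from 30 mouse cultures was hybridised to 1-colour (Cy3) Agilent oligonucleotide arrays, 4 arrays to a slide. The 10 groups, with 3 independent cultures each, were bone marrow mesenchymal stem cells (BM-MSCs) and adipose mesenchymal stem cells (ASCs) of wild-type, p53-deficient and p53- and Rb-deficient (double mutant) genotype, and the cell lines grown out of tumours that the 4 mutant cultures formed in mice. Per the labels, all strains had the FVB background, cultures were used between passages 5 and 15, and the mutant cultures were made from strains with floxed alleles by an adenovirus carrying Cre. The number of animals behind each set of 3 cultures was not stated, so the p-values measure the spread between cultures, not between animals.

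For each array the authors deposited the output of Agilent Feature Extraction 10.7.3.1, and per the file headers the processed Cy3 signal is an intensity after background subtraction and detrending, with no scaling between arrays. The authors also deposited a value table in log2 units, with no word on its scaling. Its columns had nearly equal medians, 9.68 to 9.72, and correlated across probes with the log2 processed signal of the same array at r = 0.984 to 0.997, with slopes of 0.728 to 0.892. That table lacks 2348 of the 41174 probes and was used as an alternative only.

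Spots for controls and spots marked as outliers by the software were left out, spots of a probe were averaged, and the log2 signal was scaled by subtracting the log2 of the array's 75th percentile. A value of 0 therefore means a signal at that percentile of the array. A probe was kept when it was well above background on all 3 arrays of at least 1 group, which held for 35134 probes. Probes were named by the RefSeq identifiers in the annotation of the arrays, paired with symbols of the mouse GRCm38.p6 annotation, which was used for names only. The headers place probes on the older mm8 build, and no position was converted. In all 27302 probes gained a gene name (18508 genes) and 13872 did not and were left out of the tests. The arrays came with 2 annotation versions, which differed for 7463 probes and named different genes for 16. Where a gene had several kept probes, as 6686 named genes had several probes on the array, the probe with the highest mean over all arrays stood for the gene, and 17094 genes were tested.

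The 75th percentile signal was 8904 to 21065 on 26 arrays and 37026 to 124223 on the other 4, which are BM p53 mutant replicate 2 and the 3 arrays of the tumour line of the BM double mutant. On these over-bright arrays 7.42% to 26.9% of spots were marked as outliers, against at most 0.593% on the others. The share of spots well above background was 68.1% to 86.4%, the log2 range from the median signal to the top percentile was 8.30 to 9.57, and 0 spots were marked as saturated. On the 4 over-bright arrays the top percentile signal, 779338 to 812327, was above the array's saturation value (778107 to 778168), so saturation of bright spots there is not excluded. With 3 arrays per group, their number limits the precision.

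Differences were tested with limma 3.58.1 in R 4.3.3 by 1 linear model with a mean per group over all 30 arrays (20 residual degrees of freedom), contrasts, and empirical Bayes moderation. The tests were two-sided, with Benjamini-Hochberg adjustment over all genes within each comparison, and a gene passes at an adjusted p under 0.05. The 13 comparisons set mutants against wild type, double against single mutants, ASCs against BM-MSCs and tumour lines against their parent cultures. A further 4 contrasts tested whether an effect differed between the tissues. Differences are log2 values, the first-named group minus the second, and the error given with ± is the standard error of the difference in that model, with n = 3 cultures per group unless stated. That error pools the spread of all 10 groups, so it does not measure the spread of a single group.

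The 26 gene lists covered pathways, lineages and markers of other cell types. They were tested by limma's camera statistic with a preset correlation of 0.01, two-sided and adjusted over the lists of a comparison. Because outlier spots left missing values, the test was run in an own implementation of the same formula. On 9951 genes without missing values the largest difference in log10 p from limma's camera was 1.08e-06. The test was repeated with a correlation estimated from the residuals. Of 442 list tests 129 passed with the preset correlation, and 4 of these also passed with an estimated correlation. These 4 are p53 targets in BM p53 and Rb loss, ASC p53 loss and ASC p53 and Rb loss, and E2F targets in BM p53 and Rb loss. Results with an estimated correlation are therefore given beside the list calls, and for the 29 calls of differences between tissues adjusted p was then at least 0.979.

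Groups, comparisons, tests, lists, the filter, the alternatives and the rule for naming genes were fixed before the data were examined, except for alternatives identified as later choices. For every comparison the rule named Trp53 and Rb1, and the 6 genes (4 in secondary comparisons) with the largest rise and fall among those that passed. These had to have no overlap between the groups, a probe well above background on all 3 arrays of the brighter group, and an official-style symbol. It also named up to 4 members of each list with the largest change past the test, and the 4 largest differences between tissues in each direction. Of those list members the text prints examples. Where a probe was well above background on 0 of 3 arrays of the dimmer group, the change is given as "at least", computed against the background limit of those arrays.

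The arrays were scanned in 4 sessions, on 9 slides of which 1 was scanned a second time, and each group lies in 1 session. In 4 comparisons both groups shared a session and all 3 of their slides: BM p53 and Rb loss, ASC p53 loss, the tissues in the double mutant, and the ASC double mutant tumour line. These were also fitted with slide as a block, and their directions were read within each slide. In the other 9 comparisons session and group cannot be told apart. Whether equal replicate numbers mark pairs was checked by correlating residuals. Only ASC p53 loss, whose equal numbers share slides, had every such correlation above 0.1 (0.11, 0.21 and 0.22), and its blocked count stands beside its result.

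Alternatives covered background correction, scaling, the value table of the authors, filters, the probe for a gene, the moderation, the arrays in the fit, blocks and left-out replicates. After seeing the data, fits without the 4 over-bright arrays, with array brightness as a covariate and with outlier spots kept were added, and slide-blocked fits for lists and named genes. The normexp alternative used median signals. The test was tried on simulated, independent genes in BM p53 and Rb loss. Of 50 each shifted by 1, 2 and 4 log2 units 16, 38 and 49 were called, with 7 false calls. A shifted list was called at adjusted p = 1.11e-14, with 0 other lists of 26, leaving correlated genes untested. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 read the arrays and drew the plots. The names of 13872 probes and the DNA of the lines were not analysed here.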

Results

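Gene expression was measured in 30 mouse cultures on 1-colour arrays, with 3 cultures in each of 10 groups. The groups were BM-MSCs and ASCs that were wild type, p53-deficient or deficient in both p53 and Rb (double mutant), and cell lines grown from the tumours that each of the 4 mutant cultures formed under the skin of immunodeficient mice. The comparisons ask what loss of p53 and of Rb changes in MSCs of either tissue, how the tissues differ, and how the tumour lines differ from the cultures that were injected. Per array 43379 spots were read and 17094 genes could be tested, and the signal at the 75th percentile ran from 8904 to 124223. The BM p53 mutant replicate 2 and all 3 arrays of the BM double mutant tumour line were over-bright. List medians are given relative to the median of all genes, and "2 of 3 dim" after a value counts the arrays of the dimmer group that were well above background. In 4 comparisons the groups shared slides, and in the other 9, and in the 4 differences between tissues, scan session and group cannot be told apart. Genes named for the size of their change had no overlap between the 3 values of each group.

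The Trp53 probe A_52_P491849 stood at 0.53 ± 0.07 (log2, SD, n = 3) in wild-type BM-MSCs and was lower in the mutants and tumour lines, with 0 of 3 arrays well above background in the BM double mutant tumour line. Its log2 change was -5.77 ± 0.41 in BM p53 loss, -7.45 in BM p53 and Rb loss, -8.0 in ASC p53 loss and -7.39 in ASC p53 and Rb loss, with adjusted p of at most 1.63e-10. By the fixed rule probe A_52_P781398, dimmer in wild-type BM-MSCs (-1.79), stood for Trp53. It gave 1.51 ± 0.57 in BM p53 loss (adjusted p = 0.0313), -0.40 in BM p53 and Rb loss (0.709), -1.05 in ASC p53 loss (0.178) and 0.20 in ASC p53 and Rb loss (0.816). The first was 0.29 (adjusted p = 0.285) without BM p53 mutant replicate 2 and 2.31 without replicate 1, and did not pass without wild-type replicate 2 or 3 (0.0675 and 0.0927). The mean over the Trp53 probes turned it to -2.13. Which part of the transcript each probe reads was not given, so a probe that kept its level checks nothing. Rb1 (probe A_51_P136888) fell in both double mutants, with -3.47 ± 0.31 in BM-MSCs (adjusted p = 1.33e-08) and -4.15 ± 0.31 in ASCs (adjusted p = 2.97e-10). It was also lower in the single mutants, at -0.98 (adjusted p = 0.0118; -0.42 and 0.140 without BM p53 mutant replicate 2) in BM-MSCs and -1.17 (adjusted p = 0.00522) in ASCs. A further Rb1 probe, A_52_P419873, gave -0.76 (adjusted p = 0.193) in the BM and -2.25 (adjusted p = 8.64e-05) in the ASC double mutant, and -0.55 (0.247) and -0.85 (0.118) in the single mutants. Against the single mutants Rb1 changed by -2.50 in BM-MSCs and -2.97 in ASCs (-0.21, adjusted p = 0.670, and -1.41, adjusted p = 0.0105, by the further probe). In the tumour lines it changed by -0.19 (adjusted p = 0.639) in BM p53, -1.55 (0.000153) in BM double, -1.03 (0.0147) in ASC p53 and -0.42 (0.359) in ASC double. The further probe gave -1.19 (0.0196), -2.49 (1.16e-05), -1.76 (0.0018) and -0.00479 (0.994).

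**Figure D1:**
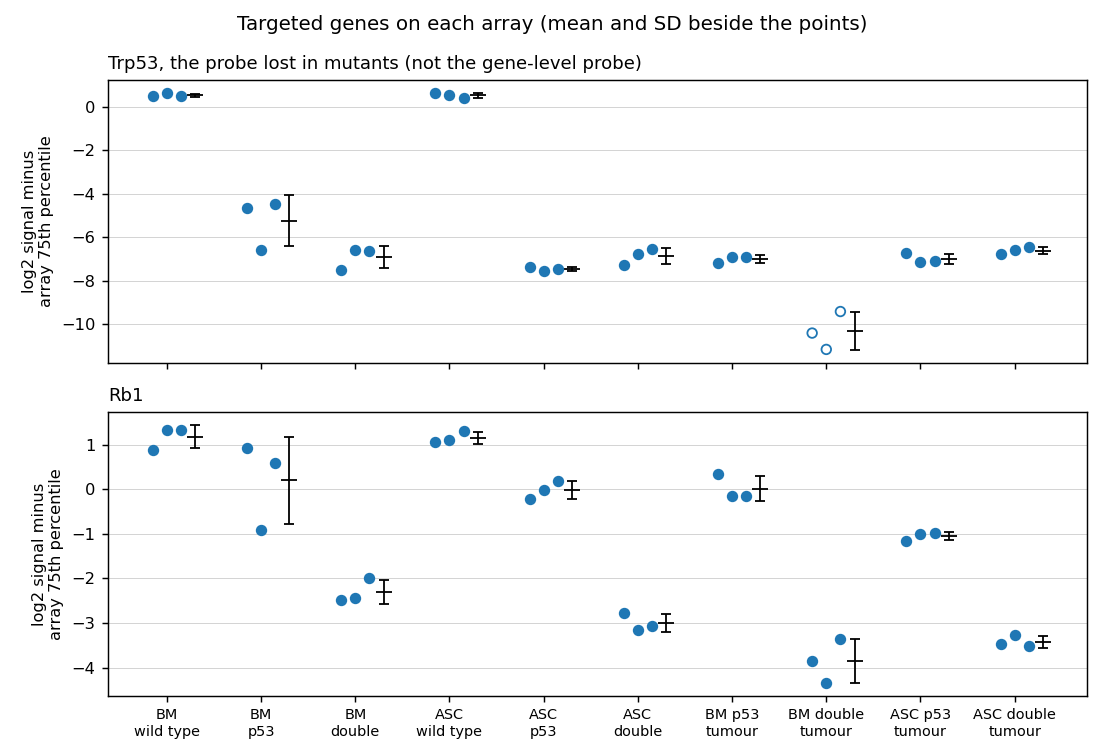
Log2 signal minus the array's 75th percentile for Trp53 (the probe lost in mutants) and Rb1 on each of the 30 arrays, with groups on the x axis and mean and SD of 3 arrays beside the points. Open circles were not well above background, and Trp53 stands at 0.53 ± 0.07 in wild-type BM-MSCs.

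In BM-MSCs, p53 loss went with a fall of p53 targets and a rise of interferon-stimulated genes. Of 32 p53 targets 0 rose, 26 fell and 6 did not pass (median -1.06, adjusted p = 1.49e-06, and adjusted p = 0.0956 with an estimated correlation). Those that fell included the cell death gene Perp (-6.92 ± 0.47), the receptor Eda2r (-6.37 ± 0.38), the cyclin-dependent kinase inhibitor Cdkn1a (-5.26 ± 0.51) and the death receptor Fas (-3.78 ± 0.32). Of 31 interferon-stimulated genes 23 rose, 0 fell and 8 did not pass (median 1.97, adjusted p = 4.03e-14, and adjusted p = 0.748 with an estimated correlation), led by the antiviral synthetase genes Oas1a (7.21 ± 0.33) and Oas2 (6.49 ± 0.54). Adipogenic genes lay higher, with 12 that rose and 4 that fell of 25 (median 0.90, adjusted p = 4.54e-05, and adjusted p = 0.748 with an estimated correlation). Among them were lipoprotein lipase, Lpl (5.19 ± 0.44, n = 2 in the first group), adiponectin, Adipoq (4.95 ± 0.35, n = 2 in the first group) and the fatty acid carrier Fabp4 (2.58 ± 0.18). Chondrogenic genes lay lower, with 1 that rose and 15 that fell of 22 (median -1.56, adjusted p = 0.0165, and adjusted p = 0.967 with an estimated correlation). Among them were fibromodulin, Fmod (-7.87 ± 0.47) and matrilin Matn3 (-3.57 ± 0.45). The largest rises of single genes, besides the synthetases, were in Nxph2 (at least 55-fold higher), Coch (at least 105-fold higher), the X-linked homeobox gene Rhox5 (6.09 ± 0.21) and the ribosomal protein gene Rps4l (5.97 ± 0.28). The largest falls were in the imprinted non-coding RNA Rian (at least 1033-fold lower), its neighbour Meg3 (-10.17 ± 0.60), Svop (at least 565-fold lower), Brinp3 (-9.88 ± 0.73, 2 of 3 dim), Inka2 (at least 228-fold lower) and the retinaldehyde dehydrogenase Aldh1a3 (-8.98 ± 0.49, 2 of 3 dim). Genes named here had adjusted p of at most 1.1e-06. By limma 9188 of 17093 genes passed, 2750 higher and 6438 lower, 6371 of them by at least 2-fold. The median over genes was -0.43, and -0.16 without BM p53 mutant replicate 2. The 29.9% of passing genes that were higher became 43.1% with normexp background correction, 42.5% with quantile scaling, 44.5% in the authors' value table and 42.4% with array brightness as a covariate. The count was 5219 with normexp background correction and 3001 with only the groups compared in the fit. List calls that ended in other settings were chondrogenic genes (in 3 of 14). When adjusted over the list alone the counts were the same for each list.

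With p53 and Rb both lost, BM-MSCs had higher replication and mitotic genes. Of 44 E2F targets and DNA replication genes 38 rose, 0 fell and 6 did not pass (median 1.37, adjusted p = 3.72e-24, and adjusted p = 0.0397 with an estimated correlation). Among them were dihydrofolate reductase, Dhfr (1.90 ± 0.17), the replication protein Gins1 (1.85 ± 0.23) and the repair protein Rad51ap1 (1.77 ± 0.23). Of 31 mitotic genes 30 rose, 0 fell and 1 did not pass (median 1.34, adjusted p = 6.52e-20, and adjusted p = 0.123 with an estimated correlation). Among them were the mitotic kinase Aurkb (1.93 ± 0.18), the transcription factor Foxm1 (1.64 ± 0.21) and the kinesin Kif2c (1.62 ± 0.15). Of 32 p53 targets 3 rose, 19 fell and 10 did not pass (median -0.84, adjusted p = 1.04e-09, and adjusted p = 0.0198 with an estimated correlation). Falls included Eda2r (-5.76 ± 0.38), Perp (-5.28 ± 0.47), Cdkn1a (-4.51 ± 0.51) and the apoptosis gene Pmaip1 (-3.47 ± 0.45). Markers of another cell type moved with these groups: of 21 haematopoietic and macrophage markers 17 rose, 0 fell and 4 did not pass (median 3.35, adjusted p = 4.62e-16, and adjusted p = 0.174 with an estimated correlation). Among them were Cd52 (7.38 ± 0.82), the pan-leukocyte phosphatase Ptprc (6.83 ± 0.65), the signalling adaptor Tyrobp (6.31 ± 0.67) and complement C1qc (6.14 ± 0.64). Here the Y-linked Ddx3y read -5.27 ± 0.40, against 0.03 ± 0.17 in wild type (SD, n = 3), so cell sex may differ too. Interferon-stimulated genes also lay higher, 10 of 31 rising and 0 falling (median 0.69, adjusted p = 0.000153, and adjusted p = 0.799 with an estimated correlation). Matrix genes (1 rose, 12 fell of 35, median -0.39, adjusted p = 0.00484) and imprinted genes (3 rose, 9 fell of 22, median -0.47, adjusted p = 0.00524) lay lower. Chondrogenic genes (1 rose, 10 fell of 22, median -0.39, adjusted p = 0.00524) and MSC surface genes (0 rose, 5 fell of 20, median -0.19, adjusted p = 0.00826) lay lower. Hypoxia genes (0 rose, 9 fell of 29, median -0.12, adjusted p = 0.0125) and epithelial markers (0 rose, 5 fell of 13, median -0.36, adjusted p = 0.0142) lay lower. Smooth muscle genes (1 rose, 6 fell of 20, median -0.28, adjusted p = 0.0213) and Schwann markers (1 rose, 7 fell of 17, median -0.56, adjusted p = 0.034) lay lower. These lists had adjusted p from 0.799 to 0.834 with an estimated correlation. Their members that fell included decorin, Dcn (-2.77 ± 0.44), the imprinted gene Peg3 (at least 29.6-fold lower), lubricin, Prg4 (-4.25 ± 0.44), the surface proteins Mcam (-4.82 ± 0.48), Eng (-3.87 ± 0.39) and Thy1 (-2.55 ± 0.23), of which Peg3 did not pass with normexp, nor Thy1 with the mean of its probes. Unlike the 12 matrix genes that fell, the fibrillin gene Fbn2 (5.88 ± 0.26) rose. The largest rises of single genes were in the Fc receptor Fcgr1 (9.01 ± 0.60, 2 of 3 dim), the chemokine Ccl3 (8.94 ± 0.65, 1 of 3 dim), Tmem273 (at least 149-fold higher), macrophage elastase, Mmp12 (at least 67-fold higher), Clec5a (7.99 ± 0.60) and Samsn1 (at least 69.9-fold higher). The largest falls of single genes were in Cpz (at least 139-fold lower), Svop (-7.89 ± 0.64, 2 of 3 dim), Aldh1a3 (-7.78 ± 0.49), Nkain4 (-7.74 ± 0.67, 2 of 3 dim), Robo3 (-7.60 ± 0.51, 1 of 3 dim) and Ackr4 (at least 55.5-fold lower). Adjusted p was at most 3.38e-05 for the genes named. By limma 4419 of 17094 genes passed, 2205 higher and 2214 lower, 2459 of them by at least 2-fold. With a slide block 5570 genes passed, and within slides at least 99.9% of genes picked on these arrays kept direction. The count was 2862 with normexp background correction and 6977 without the 4 over-bright arrays. Other settings ended the list calls of MSC surface genes (in 2 of 15), epithelial markers (in 1 of 15) and Schwann markers (in 5 of 15), with adjusted p = 0.0593 for MSC surface genes under the slide block, which is also the replicate block here. Adjusted over the list alone the counts were the same except for p53 targets (3 rose, 21 fell), E2F targets (43 rose, 0 fell), mitotic genes (31 rose, 0 fell), smooth muscle genes (1 rose, 7 fell), interferon-stimulated genes (11 rose, 0 fell) and epithelial markers (0 rose, 6 fell).

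Set against the p53 mutant, the BM double mutant had higher macrophage markers and lower interferon-stimulated genes. Ddx3y read -5.27 against -0.38, so cell sex may differ too. Of 21 haematopoietic and macrophage markers 19 rose and 0 fell (median 3.62, adjusted p = 1.12e-08). Among them were the integrin Itgam (at least 76.4-fold higher), Ptprc (8.02 ± 0.65, 2 of 3 dim), Cd52 (6.94 ± 0.82) and Laptm5 (6.88 ± 0.55, 2 of 3 dim). Of 31 interferon-stimulated genes 0 rose and 19 fell (median -1.44, adjusted p = 2.8e-08). Among them were Oas2 (-5.44 ± 0.54) and Irf7 (-3.70 ± 0.40). Of 44 E2F targets 39 rose, 1 fell and 4 did not pass (median 0.92, adjusted p = 2.8e-08), with rises such as Gins1 (2.26 ± 0.23). Of 31 mitotic genes 28 rose, 0 fell and 3 did not pass (median 0.93, adjusted p = 1.51e-07), with rises in cyclin Ccnb1 (2.38 ± 0.37) and Ttk (2.27 ± 0.33). Adipogenic genes (4 rose, 9 fell of 25, median -0.81, adjusted p = 0.0232) and hypoxia genes (2 rose, 9 fell of 29, median -0.60, adjusted p = 0.0374) lay lower. These and the lists above had adjusted p = 0.988 with an estimated correlation. Of adipogenic and hypoxia genes the fatty acid receptor Cd36 (5.20 ± 0.55, 2 of 3 dim) rose. Cfd (-2.68 ± 0.77, 1 of 3 dim) and Slc16a3 (-2.66 ± 0.39) fell. With normexp background correction Cfd turned to 0.13 (adjusted p = 0.913). The largest changes of single genes were rises in the macrophage scavenger receptor Msr1 (at least 606-fold higher), Bcl2a1b (9.20 ± 0.75, 1 of 3 dim), Rgs1 (at least 197-fold higher) and Cryzl2 (at least 157-fold higher) and falls in Inmt (-7.10 ± 0.28), laminin Lama5 (-6.15 ± 0.32), Fgf1 (at least 18.4-fold lower) and Tinagl1 (-5.99 ± 0.19). All of these had adjusted p of at most 0.00564. Fgf1 did not pass with normexp, nor Ccnb1, Ttk and Cfd with only the groups compared. By limma 9637 of 17093 genes passed, 6743 higher and 2894 lower, 6689 of them by at least 2-fold. Over genes the median was 0.46, and 0.20 without BM p53 mutant replicate 2. The 70.0% of passing genes that were higher became 54.5% with quantile scaling, 53.2% in the authors' value table and 55.1% with array brightness as a covariate. The count was 3085 with only the groups compared in the fit. List calls ended in other settings for adipogenic genes (in 1 of 14) and hypoxia genes (in 3 of 14). The counts adjusted over the list alone were the same except for hypoxia genes (1 rose, 9 fell).

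In ASCs, p53 loss went with lower p53 targets and muscle genes and with higher replication genes. Of 32 p53 targets 4 rose, 18 fell and 10 did not pass (median -1.12, adjusted p = 6.43e-08, and adjusted p = 0.0481 with an estimated correlation). Falls included Eda2r (-7.74 ± 0.38), Cdkn1a (-6.71 ± 0.51), Perp (-3.86 ± 0.47) and Dcxr (-3.15 ± 0.19). Of 44 E2F targets 31 rose, 0 fell and 13 did not pass (median 0.92, adjusted p = 1.98e-11, and adjusted p = 0.413 with an estimated correlation). Among them were the clamp loader Rfc3 (1.46 ± 0.15) and DNA polymerase Pole (1.63 ± 0.21). Of 31 mitotic genes 22 rose, 0 fell and 9 did not pass (median 1.07, adjusted p = 3.32e-10, and adjusted p = 0.467 with an estimated correlation). Among them were the spindle checkpoint kinase Bub1b (1.73 ± 0.19), Kif11 (1.68 ± 0.28) and Foxm1 (1.57 ± 0.21). Of 20 skeletal muscle genes 0 rose, 11 fell and 9 did not pass (median -1.55, adjusted p = 2.59e-07, and adjusted p = 0.467 with an estimated correlation). Of these myosin light chain Myl1 (-8.40 ± 0.48), myogenin, Myog (-7.20 ± 0.39), embryonic myosin Myh3 (-7.04 ± 0.43) and Pax3 (-5.07 ± 0.49) fell most. Interferon-stimulated genes (2 rose, 15 fell of 31, median -0.76, adjusted p = 0.0019) and hypoxia genes (1 rose, 12 fell of 29, median -0.53, adjusted p = 0.0137) lay lower. Mesenchymal factors (8 rose, 15 fell of 35, median -0.60, adjusted p = 0.0252) and matrix genes (3 rose, 13 fell of 35, median -0.60, adjusted p = 0.0322) lay lower. Epithelial markers (6 rose, 1 fell of 13, median 1.21, adjusted p = 0.0197) lay higher. These lists had adjusted p = 0.85 with an estimated correlation. Examples were Oas2 (-4.39 ± 0.54), adrenomedullin, Adm (-3.44 ± 0.46), Ebf2 (-5.52 ± 0.20), Mfap5 (-3.16 ± 0.35), Krt7 (3.08 ± 0.44) and Krt14 (2.36 ± 0.23). The interferon-inducible chemokine gene Cxcl10 (2.71 ± 0.35) rose against its list. Single genes with the largest rises were the cation channel Trpc3 (at least 1123-fold higher), the mesenchymal transcription factor Tcf21 (10.15 ± 0.39, 1 of 3 dim), Tnfaip8l3 (at least 193-fold higher), Mal2 (8.14 ± 0.51, 2 of 3 dim), Lrrc55 (at least 137-fold higher) and Slco4a1 (7.89 ± 0.64, 2 of 3 dim). The largest falls were in Brinp3 (-10.64 ± 0.73), Clec14a (at least 347-fold lower), Mab21l1 (at least 247-fold lower), the cadherin Cdh13 (-9.56 ± 0.61), Cyp2f2 (-9.05 ± 0.36) and the homeobox gene Meox2 (-8.78 ± 0.41). Adjusted p did not exceed 7.31e-05 for these. By limma 5613 of 17094 genes passed, 2788 higher and 2825 lower, 3295 of them by at least 2-fold. With a slide block, the same as a block of the replicate number here, 11437 genes passed. Of the 5613, picked on these arrays, 5610 or 5611 kept direction within each slide. The count was 11001 with only the groups compared in the fit. In other settings list calls ended for matrix genes (in 4 of 15), mesenchymal factors (in 4 of 15) and epithelial markers (in 2 of 15), with adjusted p = 0.0905 for mesenchymal factors under the slide block. Higher genes made up 49.7% of those passing and 62.5% with array brightness as a covariate. When adjusted over the list alone the counts were the same except for p53 targets (4 rose, 21 fell), E2F targets (33 rose, 0 fell), mitotic genes (26 rose, 0 fell), skeletal muscle genes (0 rose, 12 fell), matrix genes (4 rose, 15 fell), interferon-stimulated genes (2 rose, 16 fell), hypoxia genes (2 rose, 12 fell) and mesenchymal factors (8 rose, 16 fell).

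In the ASC double mutant p53 targets and muscle genes were lower and replication genes higher. Of 32 p53 targets 2 rose, 21 fell and 9 did not pass (median -1.70, adjusted p = 1.29e-07, and adjusted p = 0.0437 with an estimated correlation). Falls included Perp (-7.40 ± 0.47), Cdkn1a (-3.69 ± 0.51), Pmaip1 (-2.82 ± 0.45) and cyclin Ccng1 (-2.80 ± 0.13). Of 44 E2F targets 32 rose, 2 fell and 10 did not pass (median 0.65, adjusted p = 3.31e-07, and adjusted p = 0.648 with an estimated correlation). Among them were Chaf1b (2.13 ± 0.17), Pole (2.09 ± 0.21) and Gins2 (1.91 ± 0.16). Of 31 mitotic genes 19 rose, 0 fell and 12 did not pass (median 0.64, adjusted p = 1.08e-05, and adjusted p = 0.826 with an estimated correlation). Among them were the kinetochore protein Ndc80 (1.62 ± 0.18) and the spindle protein Tpx2 (1.67 ± 0.21). Of 20 skeletal muscle genes 0 rose, 12 fell and 8 did not pass (median -2.43, adjusted p = 5.28e-06, and adjusted p = 0.648 with an estimated correlation). Examples were Myog (-7.08 ± 0.39), Myh3 (-6.84 ± 0.43) and Myl1 (-6.47 ± 0.48). As markers of another cell type, they may also follow the mix of cells in the cultures, which was not tested. Smooth muscle genes (1 rose, 10 fell of 20, median -0.80, adjusted p = 0.00123) and MSC surface genes (3 rose, 10 fell of 20, median -0.90, adjusted p = 0.0057) lay lower. Yap and Srf targets (0 rose, 8 fell of 19, median -0.82, adjusted p = 0.0057) and mesenchymal factors (5 rose, 14 fell of 35, median -0.64, adjusted p = 0.0057) lay lower. Cytokines and proteases (3 rose, 14 fell of 28, median -0.91, adjusted p = 0.0164) and epithelial markers (0 rose, 5 fell of 13, median -0.26, adjusted p = 0.0372) lay lower. These had adjusted p from 0.648 to 0.855 with an estimated correlation. Their members that fell included Mustn1 (-3.42 ± 0.12), Eng (-4.02 ± 0.39), the stem cell factor Kitl (-3.53 ± 0.36), the immediate early gene Fos (-3.47 ± 0.26), Ebf2 (-7.38 ± 0.20) and Tbx18 (-4.87 ± 0.20). The nerve growth factor receptor gene Ngfr (5.91 ± 0.44) and the desmin gene Des (2.99 ± 0.50) rose. The largest rises of single genes were in Tecrl (11.39 ± 0.53, 2 of 3 dim), the protocadherin Pcdh10 (at least 637-fold higher), arginase, Arg1 (9.51 ± 0.54), Frmd3 (9.38 ± 1.03), the cation channel Trpc6 (9.04 ± 0.53) and Fgf12 (at least 177-fold higher). The largest falls of single genes were in Meox2 (at least 579-fold lower), the chloride channel Ano1 (at least 436-fold lower), Bst1 (at least 507-fold lower), Tdrd9 (at least 117-fold lower), Kazn (at least 275-fold lower) and Mab21l1 (at least 121-fold lower). For all of these adjusted p was at most 3.89e-05. By limma 6849 of 17094 genes passed, 3517 higher and 3332 lower, 4050 of them by at least 2-fold. Higher genes made up 51.4% of those passing, and 45.8% scaled on probes well above background on all arrays and 60.6% with array brightness as a covariate. Other settings ended the list calls of cytokines and proteases (in 2 of 14) and epithelial markers (in 5 of 14). Adjusted over the list alone the counts were the same except for cytokines and proteases (4 rose, 14 fell).

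The added loss of Rb in ASCs went with lower epithelial markers and imprinted genes. Epithelial markers (1 rose, 7 fell of 13, median -1.96, adjusted p = 0.000103) and imprinted genes (3 rose, 10 fell of 22, median -1.25, adjusted p = 0.00423) lay lower. Cytokines and proteases (4 rose, 11 fell of 28, median -0.46, adjusted p = 0.0072) and Wnt genes (5 rose, 12 fell of 25, median -1.05, adjusted p = 0.0104) lay lower. Yap and Srf targets (0 rose, 7 fell of 19, median -0.45, adjusted p = 0.0106) and smooth muscle genes (0 rose, 6 fell of 20, median -0.41, adjusted p = 0.035) lay lower. Hox and position genes (4 rose, 14 fell of 44, median -0.44, adjusted p = 0.035) lay lower. Interferon-stimulated genes (9 rose, 0 fell of 31, median 0.42, adjusted p = 0.035) lay higher. All had adjusted p = 0.984 with an estimated correlation. Their members that fell included Krt7 (-8.86 ± 0.44), Krt14 (-7.45 ± 0.23), Krt8 (-6.82 ± 0.59), the imprinted growth factor Igf2 (-8.34 ± 0.57), Magel2 (-3.30 ± 0.33) and collagenase Mmp13 (-6.19 ± 0.46). The interferon list had the immunoproteasome subunits Psmb8 (2.47 ± 0.30), Psmb9 (2.36 ± 0.31) and the peptide carrier Tap1 (2.19 ± 0.21). Against their lists, Tbx15 (4.76 ± 0.23), Shox2 (2.88 ± 0.14) and Rspo2 (4.04 ± 0.23) rose. The largest rises of single genes were in Spock3 (10.42 ± 0.54), Brinp3 (10.00 ± 0.73), Pcdh10 (8.97 ± 0.49) and osteocrin, Ostn (8.66 ± 0.36). The largest falls were in Gpm6a (-12.55 ± 0.38, 1 of 3 dim), Kazn (at least 807-fold lower), Megf6 (at least 679-fold lower) and Stk26 (-10.25 ± 0.30, 1 of 3 dim). Adjusted p stayed at or below 4.59e-06. By limma 4822 of 17094 genes passed, 2540 higher and 2282 lower, 2755 of them by at least 2-fold. The count was 3191 with normexp and 7715 without the 4 over-bright arrays. List calls ended in other settings for smooth muscle genes (in 1 of 14), Hox and position genes (in 5 of 14), interferon-stimulated genes (in 6 of 14), imprinted genes (in 1 of 14), Wnt genes (in 1 of 14) and Yap and Srf targets (in 1 of 14). The counts adjusted over the list alone were the same except for smooth muscle genes (1 rose, 7 fell), Hox and position genes (4 rose, 18 fell), interferon-stimulated genes (10 rose, 0 fell), imprinted genes (3 rose, 11 fell), Wnt genes (6 rose, 13 fell) and epithelial markers (1 rose, 8 fell).

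**Figure D2:**
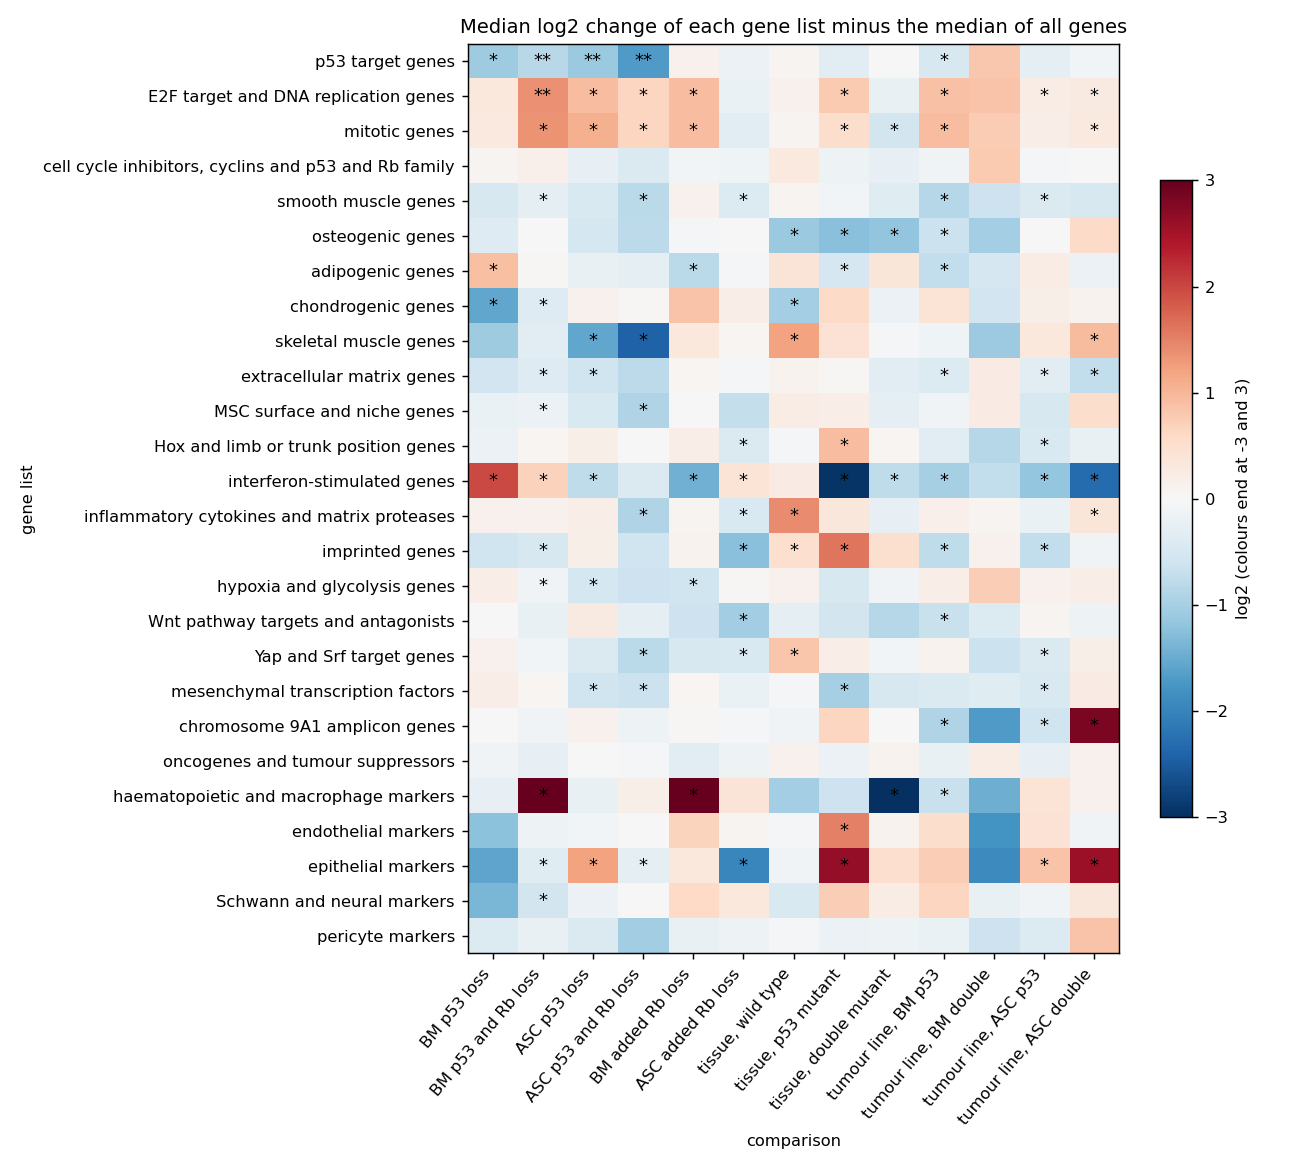
Median log2 change of each fixed gene list (y axis) minus the median of all genes in each of 13 comparisons (x axis), with colours from blue (lower) to red (higher) that end at -3 and 3. A star marks adjusted p under 0.05 with the preset correlation, and 2 stars mark the 4 calls that also pass with an estimated correlation.

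Whether an effect differed between the tissues was tested directly. For p53 loss 7614 of 17093 genes passed, 4998 higher and 2616 lower, 6159 of them by at least 2-fold, where higher means a more positive change in ASCs. For p53 and Rb loss 4846 of 17094 genes passed, 2481 higher and 2365 lower, 3649 of them by at least 2-fold. For the tumour lines of p53 mutants 4237 of 17093 genes passed, 1847 higher and 2390 lower, 3256 of them by at least 2-fold. For those of double mutants 10644 of 16392 genes passed, 7139 higher and 3505 lower, 9155 of them by at least 2-fold. The median of all genes was 0.39 in p53 loss (0.14 without BM p53 mutant replicate 2), -0.25 in the lines of p53 mutants (0.00696 without it) and 0.70 in those of double mutants. In p53 loss 65.6% of passing genes had the more positive change in ASCs and 51.4% with normexp background correction, and in p53 and Rb loss 51.2%, and 41.4% with normexp background correction and 61.2% with array brightness as a covariate. In the lines of p53 mutants it was 43.6%, and 53.6% without BM p53 mutant replicate 2 and 50.5% with normexp background correction. In the lines of double mutants the share was 67.1%, and 83.9% scaled on probes well above background on all arrays, 54.4% in the authors' value table and 39.3% with array brightness as a covariate. The count for p53 loss was 4048 with normexp. That for p53 and Rb loss was 3185 with normexp background correction, 7571 with only the groups compared in the fit, 8075 without the 4 over-bright arrays and 7549 with array brightness as a covariate. That for the lines of p53 mutants was 2176 with normexp and 6855 with array brightness as a covariate. The interferon-stimulated genes differed by a median of -2.93 in p53 loss (adjusted p = 3.64e-16, and adjusted p = 0.981 with an estimated correlation), and the haematopoietic markers by -4.15 in p53 and Rb loss (adjusted p = 4.92e-09, and adjusted p = 0.999 with an estimated correlation). Among the genes that differed most were Tcf21 (12.41 ± 0.55) and the collagen Col6a5 (-12.96 ± 0.67) in p53 loss and Arg1 (12.62 ± 0.77) and the platelet factor Pf4 (-12.10 ± 0.37) in p53 and Rb loss.

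Wild-type ASCs and BM-MSCs differed in lineage genes. Osteogenic genes were lower in ASCs, 1 rose, 14 fell and 8 did not pass of 23 (median -1.11, adjusted p = 1.52e-05, and adjusted p = 0.491 with an estimated correlation). Falls included the homeobox gene Dlx5 (-6.34 ± 0.37), alkaline phosphatase, Alpl (-5.71 ± 0.54) and osterix, Sp7 (-4.99 ± 0.52), while Smpd3 (4.99 ± 0.25) was higher. Skeletal muscle genes were higher, 10 rose, 2 fell and 8 did not pass of 20 (median 1.20, adjusted p = 8.84e-05, and adjusted p = 0.933 with an estimated correlation). Examples were Myl1 (at least 224-fold higher), Myh3 (at least 156-fold higher) and Myog (6.56 ± 0.39). Cytokines and proteases (13 rose, 4 fell of 28, median 1.42, adjusted p = 0.00913) and Yap and Srf targets (7 rose, 3 fell of 19, median 0.83, adjusted p = 0.0227) lay higher. Imprinted genes (8 rose, 1 fell of 22, median 0.50, adjusted p = 0.0334) lay higher. Chondrogenic genes (2 rose, 8 fell of 22, median -1.02, adjusted p = 0.0222) lay lower. These had adjusted p = 0.933 with an estimated correlation. Examples were complement C3 (4.83 ± 0.34), Ankrd1 (2.18 ± 0.27), Dlk1 (5.88 ± 0.43), the cartilage collagen Col11a1 (-6.18 ± 0.23) and Comp (-6.06 ± 0.36), and the collagenase gene Mmp13 (-5.69 ± 0.46) fell against its list. The largest single differences were higher levels in ASCs of cholecystokinin, Cck (at least 10284-fold higher), Olr1 (at least 1028-fold higher), Upk3b (at least 1995-fold higher), Lrrn4 (at least 702-fold higher), Foxa2 (at least 1033-fold higher) and S100g (10.88 ± 0.60), and lower levels of Rpl39l (at least 13843-fold lower), the Y-linked Eif2s3y (at least 1153-fold lower), the Y-linked Ddx3y (at least 761-fold lower), Eya2 (-11.05 ± 0.28, 2 of 3 dim), the transferrin receptor Tfr2 (-9.65 ± 0.40) and Hnmt (at least 207-fold lower). The Y-linked genes mark male cells, and wild-type ASCs had 0 arrays of 3 well above background for both while Xist, the X-inactivation transcript, read 2.35 ± 0.15 (SD, n = 3). Wild-type BM-MSCs had both kinds, with Xist at 1.56 ± 0.26 (SD, n = 3) and Ddx3y at 0.03 ± 0.17 (SD, n = 3). Adjusted p of the genes named was at most 1.03e-06. By limma 4731 of 17094 genes passed, 2179 higher and 2552 lower, 2761 of them by at least 2-fold. Over genes the median was -0.13. The count was 2905 with normexp background correction, 8863 with only the groups compared in the fit and 8019 without the 4 over-bright arrays. In other settings list calls ended for imprinted genes (in 2 of 14) and Yap and Srf targets (in 2 of 14). When adjusted over the list alone the counts were the same except for osteogenic genes (2 rose, 15 fell), chondrogenic genes (2 rose, 10 fell), skeletal muscle genes (11 rose, 3 fell), cytokines and proteases (15 rose, 4 fell) and Yap and Srf targets (10 rose, 3 fell).

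Between the p53 mutants of the 2 tissues, ASCs had lower interferon-stimulated and adipogenic genes and higher epithelial markers. Of 31 interferon-stimulated genes 0 rose, 28 fell and 3 did not pass (median -2.95, adjusted p = 4.7e-16, and adjusted p = 0.728 with an estimated correlation). E2F targets (37 rose, 1 fell of 44, median 0.79, adjusted p = 1.4e-05) and epithelial markers (11 rose, 0 fell of 13, median 2.64, adjusted p = 5.59e-05) lay higher in ASCs. Mitotic genes (23 rose, 0 fell of 31, median 0.53, adjusted p = 0.000249) and imprinted genes (13 rose, 1 fell of 22, median 1.61, adjusted p = 0.000495) lay higher in ASCs. Hox and position genes (26 rose, 7 fell of 44, median 0.93, adjusted p = 0.00679) and endothelial markers (14 rose, 1 fell of 17, median 1.52, adjusted p = 0.0189) lay higher in ASCs. Osteogenic genes (4 rose, 12 fell of 23, median -1.24, adjusted p = 0.000441) and adipogenic genes (5 rose, 11 fell of 25, median -0.50, adjusted p = 0.00665) lay lower. Mesenchymal factors (11 rose, 17 fell of 35, median -0.99, adjusted p = 0.019) lay lower. These lists had adjusted p from 0.728 to 0.988 with an estimated correlation. The mean of the mesenchymal factors was 0.32 and so of the opposite sign. Higher members included Krt18 (10.94 ± 0.87), Krt8 (9.34 ± 0.59), Kif11 (2.30 ± 0.28), Rian (at least 1195-fold higher), Meg3 (9.16 ± 0.60), Hoxb2 (8.19 ± 0.35) and the endothelial receptor Flt1 (4.16 ± 0.30). The largest single differences were Upk3b (at least 9034-fold higher), Foxa2 (at least 8066-fold higher), Vat1l (at least 6142-fold higher) and Lrrn4 (at least 5063-fold higher) on the higher side and Ddx3y (at least 882-fold lower), Edil3 (-11.68 ± 0.23), Rpl39l (-10.86 ± 0.44, 2 of 3 dim) and Col6a5 (-10.44 ± 0.47) on the lower. Named genes had adjusted p of 8.5e-07 or less. By limma 8856 of 17093 genes passed, 5552 higher and 3304 lower, 6168 of them by at least 2-fold. The median over genes was 0.29, and 0.0358 without BM p53 mutant replicate 2. Of passing genes 62.7% were higher, and 49.8% with normexp background correction. The count was 5660 with normexp and 4977 with only the groups compared in the fit. Other settings ended the list calls of adipogenic genes (in 1 of 14), Hox and position genes (in 2 of 14), mesenchymal factors (in 2 of 14) and endothelial markers (in 2 of 14). Adjusted over the list alone the counts were the same except for mitotic genes (25 rose, 1 fell), osteogenic genes (4 rose, 13 fell), Hox and position genes (27 rose, 9 fell), mesenchymal factors (11 rose, 18 fell) and endothelial markers (14 rose, 2 fell).

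Between the double mutants, ASCs had lower macrophage markers than BM-MSCs. Of 21 haematopoietic and macrophage markers 1 rose, 17 fell and 3 did not pass (median -3.68, adjusted p = 9.8e-11, and adjusted p = 0.801 with an estimated correlation). Examples were Ptprc (at least 321-fold lower), C1qc (-9.44 ± 0.64, 1 of 3 dim), Tyrobp (-8.83 ± 0.67, 2 of 3 dim) and the macrophage receptor Adgre1 (-8.36 ± 0.45, 1 of 3 dim). Osteogenic genes (3 rose, 12 fell of 23, median -1.19, adjusted p = 0.00022) and mitotic genes (0 rose, 15 fell of 31, median -0.54, adjusted p = 0.00524) lay lower in ASCs. Interferon-stimulated genes (2 rose, 13 fell of 31, median -0.75, adjusted p = 0.0181) lay lower in ASCs. These had adjusted p from 0.801 to 0.897 with an estimated correlation. Examples were Dlx5 (-9.08 ± 0.37), Phex (-5.49 ± 0.39), Cenpf (-1.86 ± 0.24), Foxm1 (-0.98 ± 0.21), Gbp3 (-2.66 ± 0.33) and Rtp4 (-2.23 ± 0.40). Against its list Oasl1 (2.33 ± 0.35) was higher. The largest single differences were Vat1l (at least 4093-fold higher), Spock3 (at least 2891-fold higher), Tecrl (at least 2484-fold higher) and Heph (11.52 ± 0.59, 2 of 3 dim) on the higher side and Rpl39l (at least 12961-fold lower), Pf4 (at least 1893-fold lower), Ccl3 (at least 845-fold lower) and Eya2 (-11.58 ± 0.28, 1 of 3 dim) on the lower. The highest adjusted p among them was 0.000733. By limma 6355 of 17094 genes passed, 3134 higher and 3221 lower, 3896 of them by at least 2-fold. With a slide block 8054 genes passed, and within slides at least 99.4% of genes picked on these arrays kept direction. The interferon list kept its direction on 2 of 3 slides, with values of -1.45 to 0.21. Higher genes made up 49.3% of those passing, and 39.6% with normexp background correction and 60.7% with array brightness as a covariate. List calls ended in other settings for mitotic genes (in 2 of 15) and interferon-stimulated genes (in 1 of 15). The counts adjusted over the list alone were the same except for mitotic genes (0 rose, 17 fell) and interferon-stimulated genes (2 rose, 15 fell).

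The tumour line of the BM p53 mutant had higher replication and mitotic genes than its parent. Of 44 E2F targets 38 rose, 0 fell and 6 did not pass (median 0.88, adjusted p = 5.42e-11, and adjusted p = 0.644 with an estimated correlation). Examples were cyclin Ccne2 (2.47 ± 0.42) and Rad51ap1 (2.25 ± 0.23). Of 31 mitotic genes 28 rose, 0 fell and 3 did not pass (median 0.92, adjusted p = 4.13e-09, and adjusted p = 0.644 with an estimated correlation). Examples were Ccnb1 (2.40 ± 0.37) and Nek2 (1.91 ± 0.25). Interferon-stimulated genes (0 rose, 13 fell of 31, median -1.0, adjusted p = 1.56e-05) and Wnt genes (4 rose, 9 fell of 25, median -0.66, adjusted p = 0.000752) lay lower. Matrix genes (0 rose, 10 fell of 35, median -0.41, adjusted p = 0.001) and adipogenic genes (3 rose, 11 fell of 25, median -0.74, adjusted p = 0.001) lay lower. Imprinted genes (3 rose, 8 fell of 22, median -0.75, adjusted p = 0.00934) and smooth muscle genes (2 rose, 7 fell of 20, median -0.85, adjusted p = 0.00934) lay lower. Chromosome 9 segment genes (0 rose, 5 fell of 11, median -0.89, adjusted p = 0.0109) and osteogenic genes (5 rose, 8 fell of 23, median -0.65, adjusted p = 0.0115) lay lower. Haematopoietic markers (3 rose, 8 fell of 21, median -0.66, adjusted p = 0.0429) and p53 targets (6 rose, 10 fell of 32, median -0.49, adjusted p = 0.0493) lay lower. These lists had adjusted p from 0.644 to 0.945 with an estimated correlation. Members that fell included the RNA sensor Ifih1 (-2.08 ± 0.30), the Wnt antagonist Sfrp2 (-5.92 ± 0.49), lumican, Lum (-5.03 ± 0.37), periostin, Postn (-3.66 ± 0.50) and Mest (-5.88 ± 0.33). The receptor gene Eda2r (2.21 ± 0.38, another probe not passing) rose against its list. The largest rises of single genes were in the X-linked genes Xlr4b (6.46 ± 0.61, 2 of 3 dim, another probe not passing), Xlr3c (at least 39.1-fold higher), the pluripotency factor Sox2 (at least 22.8-fold higher), Sh2d1b1 (5.11 ± 0.56), S100a7a (5.02 ± 0.61) and prostacyclin synthase, Ptgis (4.90 ± 0.36). The largest falls of single genes were in Itm2a (-10.47 ± 0.36), Lgr5 (-10.33 ± 0.73, 1 of 3 dim), Rpl39l (-9.38 ± 0.44), Wdr72 (at least 83.6-fold lower), Nxph2 (at least 77.3-fold lower) and Fbn2 (at least 152-fold lower). Among the named genes adjusted p reached 7.87e-05, and Ccne2, Ccnb1, Nek2, Postn, Eda2r, Sox2 and S100a7a did not pass with only the groups compared. By limma 7798 of 17093 genes passed, 5045 higher and 2753 lower, 4946 of them by at least 2-fold. Over genes the median was 0.31, and 0.0323 without BM p53 mutant replicate 2. Of passing genes 64.7% were higher, 45.2% with only the groups compared in the fit, 52.0% without BM p53 mutant replicate 2 and 54.1% with array brightness as a covariate. The count was 4761 with normexp and 877 with only the groups compared in the fit. In other settings list calls ended for p53 targets (in 6 of 14), smooth muscle genes (in 1 of 14), osteogenic genes (in 5 of 14), imprinted genes (in 2 of 14), chromosome 9 segment genes (in 2 of 14) and haematopoietic markers (in 3 of 14). When adjusted over the list alone the counts were the same except for p53 targets (6 rose, 11 fell), E2F targets (39 rose, 0 fell), osteogenic genes (5 rose, 10 fell), adipogenic genes (3 rose, 12 fell) and interferon-stimulated genes (0 rose, 12 fell).

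In the tumour line of the BM double mutant more genes were lower than higher, on 3 over-bright arrays. By limma 11904 of 16392 genes passed, 3811 higher and 8093 lower, 9090 of them by at least 2-fold, with the median of all genes at -0.69. The share of passing genes that were higher was 32.0%, and 14.8% scaled on probes well above background on all arrays, 44.9% in the authors' value table and 61.8% with array brightness as a covariate, so the majority turned with the covariate and with none of these scalings. The largest rises were in the Dickkopf gene Dkk2 (9.16 ± 0.72), carbonic anhydrase Car6 (7.47 ± 0.45), the urea carrier Slc14a1 (6.54 ± 0.43, 2 of 3 dim), the Wnt agonist Rspo1 (6.35 ± 0.45), Jhy (at least 22.6-fold higher) and the calcium channel Cacna1g (6.15 ± 0.46). The largest falls were in Xlr4b (at least 399-fold lower), Sorbs2 (at least 184-fold lower), Igf2 (at least 324-fold lower), the transcription factor Foxp2 (-9.19 ± 0.44), the homeobox gene Hoxa11 (-9.13 ± 0.37, 2 of 3 dim) and Syce1 (at least 81.8-fold lower), with adjusted p of at most 1.1e-07, and Jhy did not pass with normexp or without the filter on dim probes. No list of 26 passed, and 5 had an unadjusted p under 0.05. The lowest adjusted p, 0.0699, was shared by 4 lists, E2F targets (13 rose, 8 fell of 44), hypoxia genes (11 rose, 9 fell of 28), interferon-stimulated genes (0 rose, 20 fell of 31) and haematopoietic markers (0 rose, 15 fell of 20), each with adjusted p = 0.968 with an estimated correlation.

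The tumour line of the ASC p53 mutant had lower interferon-stimulated genes than its parent. Of 31 such genes 2 rose, 19 fell and 10 did not pass (median -1.17, adjusted p = 2.93e-07, and adjusted p = 0.932 with an estimated correlation). Examples were Ifi44 (-4.37 ± 0.57), Rtp4 (-3.92 ± 0.40) and Parp14 (-3.10 ± 0.49). Imprinted genes (1 rose, 10 fell of 22, median -0.73, adjusted p = 0.000143) and Hox and position genes (3 rose, 15 fell of 44, median -0.46, adjusted p = 0.0012) lay lower. Matrix genes (2 rose, 10 fell of 35, median -0.31, adjusted p = 0.0012) and chromosome 9 segment genes (1 rose, 8 fell of 11, median -0.59, adjusted p = 0.00619) lay lower. Mesenchymal factors (2 rose, 10 fell of 35, median -0.45, adjusted p = 0.0111) and smooth muscle genes (1 rose, 7 fell of 20, median -0.44, adjusted p = 0.0146) lay lower. Yap and Srf targets (0 rose, 5 fell of 19, median -0.44, adjusted p = 0.0417) lay lower. Epithelial markers (4 rose, 0 fell of 13, median 0.85, adjusted p = 0.0264) and E2F targets (12 rose, 0 fell of 44, median 0.23, adjusted p = 0.0459) lay higher. These lists had adjusted p = 0.932 with an estimated correlation. Members that fell included Nnat (-5.55 ± 0.23), Plagl1 (-2.64 ± 0.19), Hoxa5 (-2.33 ± 0.14), Lum (-4.73 ± 0.37), the basement membrane collagen Col4a1 (-2.98 ± 0.15) and Fos (-1.97 ± 0.26). Those that rose included the epithelial factor Elf3 (4.30 ± 0.60), the claudin Cldn7 (3.49 ± 0.24) and the nuclease Fen1 (0.72 ± 0.16). The largest rises of single genes were in the crystallin Cryaa (7.43 ± 0.53), tenomodulin, Tnmd (7.22 ± 0.44), Dmkn (6.82 ± 0.45), Cpn1 (6.70 ± 0.30), Kif1a (6.35 ± 0.49) and Ostn (6.24 ± 0.36). The largest falls of single genes were in Rps4l (-7.45 ± 0.28), Tnik (at least 35.7-fold lower), Cxcl15 (-6.54 ± 0.71), Lhx8 (at least 30.3-fold lower), the limb factor Pitx1 (-5.85 ± 0.52) and glypican Gpc3 (-5.55 ± 0.54). No adjusted p among these was above 0.00192. By limma 5088 of 17094 genes passed, 2788 higher and 2300 lower, 2615 of them by at least 2-fold. Of passing genes 54.8% were higher. The count was 9700 with only the groups compared in the fit. It was 8252 (55.5% higher) without the 4 over-bright arrays, which lie in other groups, and 8189 (39.7% higher) with array brightness as a covariate. Other settings ended the list calls of E2F targets (in 8 of 14), smooth muscle genes (in 2 of 14), Yap and Srf targets (in 3 of 14), mesenchymal factors (in 4 of 14) and epithelial markers (in 3 of 14). Adjusted over the list alone the counts were the same except for Hox and position genes (3 rose, 17 fell), interferon-stimulated genes (3 rose, 21 fell), imprinted genes (1 rose, 12 fell), Yap and Srf targets (0 rose, 6 fell) and mesenchymal factors (4 rose, 11 fell).

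The line labelled as the tumour line of the ASC double mutant differed from its parent in sex-linked genes and in a segment of chromosome 9. The Y-linked genes were higher in the line, Eif2s3y (at least 1436-fold higher) and Ddx3y (at least 886-fold higher), and Xist (at least 2671-fold lower) was lower. Of the 11 measured genes of the chromosome 9 segment list 7 rose, 2 fell and 2 did not pass (median 2.82, adjusted p = 0.000227, and adjusted p = 0.97 with an estimated correlation), with rises in the neutrophil collagenase Mmp8 (10.01 ± 0.53, 1 of 3 dim) and Cep126 (3.80 ± 0.38) and a fall in the neighbouring Trpc6 (-7.57 ± 0.53) and Pgr (-7.49 ± 0.40). Of 31 interferon-stimulated genes 0 rose, 28 fell and 3 did not pass (median -2.32, adjusted p = 1.83e-15, and adjusted p = 0.93 with an estimated correlation). Examples were Ifi27l2a (-4.54 ± 0.33), Usp18 (-4.10 ± 0.43) and Oas1a (-3.40 ± 0.33). Epithelial markers (8 rose, 0 fell of 13, median 2.57, adjusted p = 9.41e-06) and E2F targets (19 rose, 0 fell of 44, median 0.27, adjusted p = 0.000529) lay higher. Skeletal muscle genes (9 rose, 2 fell of 20, median 0.96, adjusted p = 0.0067) and cytokines and proteases (8 rose, 4 fell of 28, median 0.36, adjusted p = 0.0122) lay higher. Mitotic genes (6 rose, 1 fell of 31, median 0.29, adjusted p = 0.0471) lay higher. Matrix genes (4 rose, 15 fell of 35, median -0.74, adjusted p = 0.00214) lay lower. These had adjusted p from 0.93 to 0.97 with an estimated correlation. Examples were the adhesion protein Cdh1 (at least 146-fold higher), Krt8 (7.22 ± 0.59), Krt14 (5.91 ± 0.23), Cdkn2c (1.89 ± 0.22), Myog (6.09 ± 0.39), troponin Tnnt2 (6.39 ± 0.46) and Mmp13 (8.27 ± 0.46). The remaining large rises were in Mal2 (at least 428-fold higher), Prl2c3 (9.36 ± 0.70) and the inflammatory caspase Casp1 (9.32 ± 0.26). The remaining large falls were in Tecrl (at least 2208-fold lower), Spock3 (-11.78 ± 0.54, 1 of 3 dim), Pitx1 (-10.98 ± 0.52, 1 of 3 dim), Gabrb1 (-10.30 ± 0.62, 1 of 3 dim) and Heph (-9.93 ± 0.59). The limit on adjusted p for the named genes was 2.79e-07. By limma 5252 of 17094 genes passed, 2608 higher and 2644 lower, 3168 of them by at least 2-fold. With a slide block 5377 genes passed, and within slides 99.2% to 99.9% of genes picked on these arrays kept direction. The list calls of cytokines and proteases (adjusted p = 0.108) and skeletal muscle genes (adjusted p = 0.0986) ended under the slide block, and calls ended in other settings for mitotic genes (in 3 of 15), skeletal muscle genes (in 2 of 15) and cytokines and proteases (in 3 of 15). The counts adjusted over the list alone were the same except for E2F targets (20 rose, 1 fell), mitotic genes (6 rose, 0 fell), skeletal muscle genes (10 rose, 2 fell), matrix genes (4 rose, 17 fell), interferon-stimulated genes (0 rose, 29 fell) and epithelial markers (9 rose, 0 fell).

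**Figure D3:**
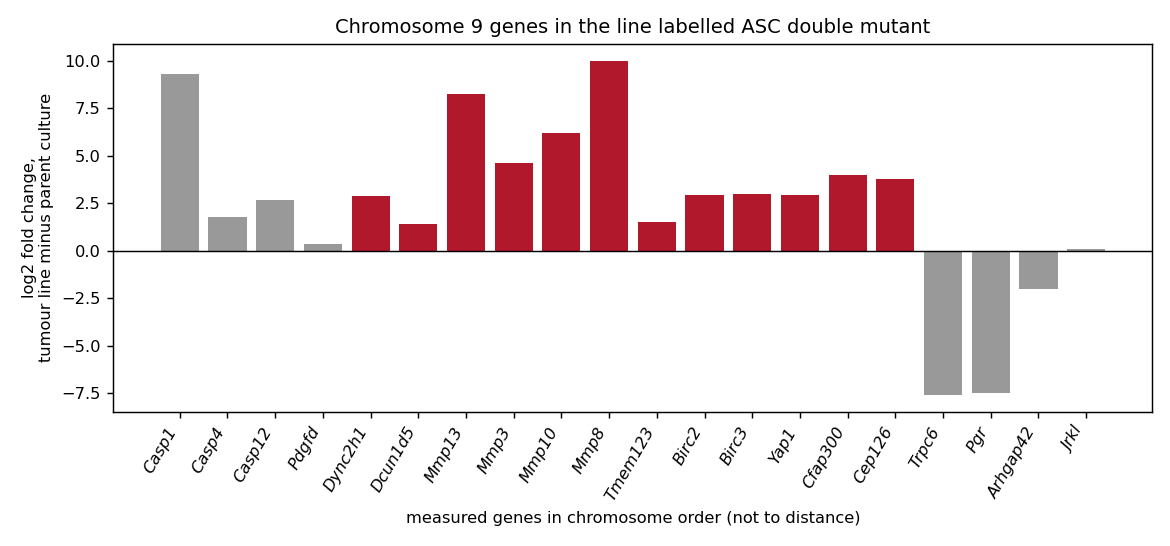
Log2 fold change of the line labelled ASC double mutant against its parent culture (y axis) for genes with a mean over -5 log2 in either group, in chromosome 9 order (x axis, not to distance), each bar a difference of means of 3 arrays. Red bars are the 12 neighbouring genes raised together, next to Trpc6 at -7.57.

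Of the fixed lists, 3 passed in none of the 17 contrasts: the cell cycle inhibitors (lowest adjusted p = 0.275), the oncogenes and tumour suppressors (0.296) and the pericyte markers (0.0542).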

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

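Tests of the patterns were chosen after their results were seen, except the random gene orders and the splits of arrays. The line labelled as the tumour line of the ASC double mutant held Y-linked transcripts (Eif2s3y at 1.35 and Ddx3y at 0.66 log2) and Xist at -10.40, while 0 of 3 arrays of its parent culture read either Y-linked gene above background. Cells of a host mouse, taken here to be wild type for p53, are argued against by the Trp53 probe lost in the mutants, which stood at 0.703% of the wild-type level (highest array 0.782%). A swap with the BM double mutant tumour line is argued against by the median position between BM (0) and ASC (1) levels over 85 genes that differ between the tissues, 0.748 in this line (arrays 0.702 to 0.747) and -0.081 in the other. Outgrowth of a minority of the arrayed parent culture, which held at most 0.0696% of the line's Eif2s3y level, may account for it and stays open, as does origin in another culture from an animal of the other sex, which was not tested. The Y-linked Kdm5d was well above background on 3 of 3 parent arrays (-7.88) but also in wild-type and p53 mutant ASCs (-8.56 and -8.65), so it does not decide this.

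In the BM double mutant tumour line 8093 of 11904 passing genes were lower, and its 3 arrays were over-bright. Across genes, which are not independent replicates, its change went with the difference between the over-bright BM p53 array and the others of that group at Pearson r = 0.630, against -0.067 to 0.037 in contrasts without over-bright arrays. Brightness may account for a share of the pattern. Growth as a tumour stays open, since 38.2% of passing genes were lower with brightness as a covariate and 38.2% to 85.2% over all settings. The brightness and the group cannot be told apart, because all 3 arrays of the line are over-bright.

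In the line labelled ASC double mutant 12 neighbouring measured genes of chromosome 9, from Dync2h1 to Cep126, were higher together, with a highest median of 3.70 over a window of 11 genes. A chance run is argued against by random gene orders, of which 0 of 1000 reached it (highest 2.56), but windows on chromosome 11 (Gm11938 to Krt14, 3.86) and 5 (Ankrd17 to Areg, 3.36) lay above that too. Induction of protease and Birc genes alone stays open, since the run's other 6 genes (median 2.81, 1.33 to 3.87) were chosen as raised. Gain of the segment may account for the run, whose lowest median against the 9 other groups was 2.46 (highest 3.53). The gain stays open, since DNA was not measured.

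The effects of several lists and genes differed between ASCs and BM-MSCs by the test of the difference itself, ASC minus BM, in log2 units and not relative to all genes. For p53 loss the median differences were 0.97 for E2F targets, 0.98 for mitotic genes, -0.47 for adipogenic genes, 2.33 for chondrogenic genes, 0.057 for skeletal muscle genes, -2.53 for interferon-stimulated genes, 1.48 for imprinted genes, -0.17 for hypoxia genes, -0.22 for mesenchymal factors and 2.73 for epithelial markers, with adjusted p of at most 0.0365. The skeletal muscle median was positive (0.20 with the brightness covariate), but -0.19 without the over-bright arrays and -0.13 with quantile scaling. The mesenchymal factors had a positive mean (0.11). Both lists were called lower, against an all-gene median of 0.39 (0.14 without BM p53 mutant replicate 2). Of 14 settings, calls ended for chondrogenic genes in 2, skeletal muscle genes in 4, imprinted genes in 2, hypoxia genes in 4, mesenchymal factors in 1 and epithelial markers in 2, and the hypoxia median was 0.12 with quantile scaling. The genes with the largest differences were 12.41 for Tcf21, 12.37 for Palmd, 11.64 for Mrap, 11.60 for Ptprb, -11.43 for Clec14a, -11.70 for Hhip, -12.05 for Mab21l1 and -12.96 for Col6a5. For p53 and Rb loss the lists gave -0.44 for E2F targets, -0.59 for mitotic genes, -0.10 for adipogenic genes, -1.76 for skeletal muscle genes, -0.95 for interferon-stimulated genes, -1.41 for cytokines and proteases, -0.58 for Yap and Srf targets, -0.68 for mesenchymal factors and -4.06 for haematopoietic markers (adjusted p at most 0.0342), and the genes 12.62 for Arg1, 11.47 for Tecrl, 9.74 for Gabrb1, 9.27 for Pcdh10, -11.64 for Dock10, -11.94 for Ccl6, -12.10 for Pf4 and -12.11 for St3gal6. Here calls ended for E2F targets in 1, mitotic genes in 2, adipogenic genes in 7, Yap and Srf targets in 3 and mesenchymal factors in 1 of 14. For the tumour lines of p53 mutants the lists gave -1.02 for E2F targets, -1.04 for mitotic genes, 0.59 for adipogenic genes, 0.97 for Wnt genes and 1.32 for haematopoietic markers (adjusted p at most 0.000975), and the genes 12.28 for Lgr5, 11.93 for Igfbp5, 11.60 for Itm2a, 11.47 for Hhip, -7.01 for Kcnh5, -7.05 for Rps4l, -7.13 for Ctnnd2 and -7.17 for Popdc3. No setting ended these 5 calls except the estimated correlation. For the lines of double mutants the lists gave 3.63 for skeletal muscle genes, -0.21 for matrix genes, -0.61 for interferon-stimulated genes, 3.08 for chromosome 9 segment genes and 3.38 for epithelial markers (adjusted p at most 0.043), and the genes 19.13 for Xlr4b, 17.20 for Xlr3c, 15.99 for Eif2s3y, 15.29 for Ddx3y, -10.85 for Xist, -11.22 for Tecrl, -11.76 for Dkk2 and -14.31 for Sdk1. Each of these 5 list calls ended in some of 13 settings, for skeletal muscle genes in 2, matrix genes in 2, interferon-stimulated genes in 4, chromosome 9 segment genes in 3 and epithelial markers in 3. All genes named passed, at adjusted p of at most 3.48e-06. No list difference passed with an estimated correlation, and differences of genes near background in a group are fitted values, not bounds.

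Of the 10 splits of the 6 arrays into 2 groups of 3, only 1, the real one, gave as many passing genes in each of the 13 comparisons, and 10 splits are too few for a share under 0.05. The highest count of another split was 1264 for BM p53 loss (real 9188), 0 for BM p53 and Rb loss (4419), 0 for ASC p53 loss (5613), 0 for ASC p53 and Rb loss (6849), 2219 for added Rb loss in BM-MSCs (9637) and 1 in ASCs (4822). Between tissues it was 0 in wild type (4731), 1091 in p53 mutants (8856) and 0 in double mutants (6355). For the tumour lines it was 3137 for BM p53 (7798), 387 for BM double (11904), 0 for ASC p53 (5088) and 2 for ASC double (5252). For differences between tissues, 100 splits within the tissues were drawn, and some turn 1 comparison round as a whole. As many genes came from 2 splits for p53 loss (highest other 8758), 2 for p53 and Rb loss (6613) and 1 for the lines of double mutants (9290), a share under 0.05, and from 7 for the lines of p53 mutants (8342), where chance is not excluded. In the other 3 chance is excluded only for the groups as a whole and not for the difference alone, since these splits also undo the effects within each tissue.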

How the results depend on the processing

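Of the settings below, those without the 4 over-bright arrays, with array brightness as a covariate, with outlier spots kept and with slide blocks for lists and genes were chosen after seeing the data. Of 13 comparisons and 4 differences between tissues, the counts of passing genes moved by over 1.5 times only as follows, and the cause was not tested except where named. With normexp background correction they were 5219 for BM p53 loss, 2862 for BM p53 and Rb loss, 3191 for added Rb loss in ASCs, 2905 and 5660 for the tissues in wild type and p53 mutant, 4761 for the BM p53 tumour line, and 4048, 3185 and 2176 for the differences in p53 loss, p53 and Rb loss and lines of p53 mutants. With only the groups compared in the fit, which has fewer arrays, they were 3001 for BM p53 loss, 11001 for ASC p53 loss, 3085 for added Rb loss in BM-MSCs, 8863 and 4977 for the tissues in wild type and p53 mutant, 877 and 9700 for the BM and ASC p53 tumour lines and 7571 for the difference in p53 and Rb loss. With a block of replicate numbers, which pair arrays without evidence except in ASC p53 loss, limma gave 0 for BM p53 loss (4470 at unadjusted p under 0.05), 11437 for ASC p53 loss, 0 for added Rb loss in BM-MSCs (4489 unadjusted), 7369 and 1271 for the tissues in wild type and p53 mutant, 0 for the BM p53 tumour line (3231 unadjusted), 9191 for the ASC p53 line, and 7857 and 2168 for the differences in p53 and Rb loss and lines of p53 mutants. With slide as a fixed block ASC p53 loss gave 11437. Without the 4 over-bright arrays they were 6977 for BM p53 and Rb loss, 7715 for added Rb loss in ASCs, 8019 for the wild-type tissues, 8252 for the ASC p53 line and 8075 for the difference in p53 and Rb loss. With the brightness covariate they were 8189 for the ASC p53 line and 7549 and 6855 for the differences in p53 and Rb loss and lines of p53 mutants. Counts at 2-fold or more, fewer by construction, were 2459 and 3295 for BM p53 and Rb loss and ASC p53 loss, 4050 for ASC p53 and Rb loss, 2755 for added Rb loss in ASCs, 2761 and 3896 for the tissues in wild type and double mutant, 4946 and 2615 for the BM and ASC p53 lines and 3168 for the ASC double line. Leaving out any 1 replicate moved no count by over 1.5 times (BM p53 loss 7779 to 9874, lines of p53 mutants 3403 to 5012). The BM double line and its difference have no value without the over-bright arrays. Trp53 in BM p53 loss turned to -2.13 with the mean of its probes, and Rb1 in the difference of the double mutant lines to -0.21 with the covariate. Cfd in added Rb loss in BM-MSCs turned to 0.13 with normexp (adjusted p 0.913). Of 8163 settings of 404 effects of single genes 7971 kept the direction and the call, 152 were weaker, 37 stronger and 3 reversed. Of 1835 settings of the 129 list calls 1684 kept the call, 151 lost it and 0 reversed, and 74 calls held in every setting with the preset correlation, while 4 of the 129 passed with an estimated one. Signal over background limits folds of dim genes to bounds, and 68.1% to 86.4% of spots were well above it.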
